A study of Rattus norvegicus with 9 samples.

How the data were processed

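RNA was sequenced from 9 cultures of rat bone marrow-derived dendritic cells kept with 10% serum, GM-CSF and IL-4, with 3 cultures in each of the groups Control, LPS and LPS+EVs. Groups and replicate numbers were taken from the sample labels. Per the labels, the authors used fastp, HISAT2, HTSeq, R 3.2.0 and the rat genome build mRatBN7.2, and the settings are not known here. The deposited table holds FPKM (fragments per kilobase of gene, scaled to the assigned reads) for 20442 genes in 9 libraries, and its gene symbols were used as given.

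FPKM values of a gene move in steps of 1 read, and these steps gave back whole reads, within 0.002 reads, for all 18833 genes seen in at least 2 libraries. The recovered totals were 32148734 to 39407293 reads per library, a 1.23-fold range. The method was tested on 6000 simulated genes and recovered 100% of them, up to any whole factor that all counts of a gene share. At these depths 3 reads in a gene of 1 kilobase correspond to 0.076 to 0.093 FPKM, a limit for counting error only. Counting error was far below the spread between replicates of a group (chi-square per degree of freedom of 45.4 or more for each pair).

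The comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The plan named a negative binomial test on read counts as the main test and, if the values were FPKM, limma-trend in its place, which is what was run. Negative binomial fits named in the plan were not run. Genes with at least 1 FPKM in at least 3 libraries (11141 genes) were kept, 1 was added to each FPKM before taking log2, and limma 3.58.1 in R 4.3.3 fitted all 9 libraries with 1 mean per group and moderated variances with a trend on mean expression. P-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Library scaling was that of the deposited FPKM.

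The 38 gene lists were written from textbook knowledge, and 34 of them had at least 5 tested genes and were tested with camera from limma, with a preset correlation of 0.01 between genes and, beside it, a correlation estimated per list. Camera asks whether the genes of a list are shifted against all other genes. Mitochondrially encoded genes and 2 further symbols were matched by synonym. Named genes are, for each comparison, those with the largest rises and falls (6 each, or 4 each for LPS+EVs against Control) among genes that passed, had no overlap between groups, a mean log2 CPM of at least 1 and a full symbol, then a panel of 16 genes, and then up to 4 members per list with the smallest adjusted p. Genes lowered or raised by LPS were counted again in LPS+EVs against LPS, beside 100 simulated data sets without an effect in which both comparisons share the LPS libraries.

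Replicate numbers were checked for pairing: after removal of group means, libraries with 1 number correlated at 0.28 to 0.86 across groups, and libraries with different numbers at -0.74 to 0.43. The cultures are therefore treated as possibly paired, and a model with the replicate number as a block is given beside a result where it changes a call.

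In simulated data with the measured spread, limma found 7.2% of 1.5-fold, 40.1% of 2-fold and 83.8% of 4-fold changes between LPS+EVs and LPS, with 4.12% false calls. With a replicate block it found 16.7%, 68.5% and 96.7%, with 4.98% false calls. Camera found a list shifted by 0.5 in 18 of 18 runs and called 5 other lists in all runs together. The simulated genes varied independently, so this does not test the preset correlation for lists whose genes vary together. Without the block the simulated libraries were independent too, unlike libraries of 1 number here, so those shares need not hold for the real comparison. Single-gene changes were simulated only in genes above about 1 FPKM in LPS.

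Choices varied from the start were median-of-ratios scaling, no filter, a filter of 1 CPM in 3 libraries, an added value of 0.1, the 6 compared libraries alone, the replicate block, a 2-fold threshold, an estimated correlation and leaving out each library in turn. Chosen after seeing the data were TMM scaling and limma-voom on recovered reads, the replicate block with median-of-ratios scaling, and libraries numbered 1 and 3 alone. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for reading and figures.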

Results

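RNA sequencing measured transcripts in 9 cultures of rat bone marrow-derived dendritic cells, the antigen-presenting cells that GM-CSF and IL-4 (20 ng/mL each) grow out of bone marrow. Control cultures (n = 3) received no treatment. LPS cultures (n = 3) received lipopolysaccharide, the bacterial endotoxin sensed through the receptor Tlr4, at 1 µg/mL, and LPS+EVs cultures (n = 3) received LPS and extracellular vesicles (EVs) derived from ASCs. The labels give a treatment time of 24 h and a further 50 ng/mL of an agent they do not name. They do not say whether this agent is the EVs, and the EV dose is not known here. Control, labelled as untreated, was taken as without this agent, and both other groups as with it, which is an assumption. If it holds, the effect of the agent cannot be told apart from that of LPS in comparisons with Control. If the agent is the EVs, the LPS cultures did not receive it. Replicates are labelled as biological, but nothing else says that they came from separate animals, so each p-value measures only the spread between these cultures. The 9 libraries held 32148734 to 39407293 reads assigned to genes. Between 9846 and 10821 genes reached 1 FPKM (fragments per kilobase of gene, scaled to the assigned reads) in each library.

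Treatment with LPS separated the libraries along the first principal component, which held 65.6% of the variance. The second component, with 21% of the variance, held apart the library numbered 2 within each group, at scores of -20.9 in Control, -41.1 in LPS and -35.9 in LPS+EVs.

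**Figure D1:**
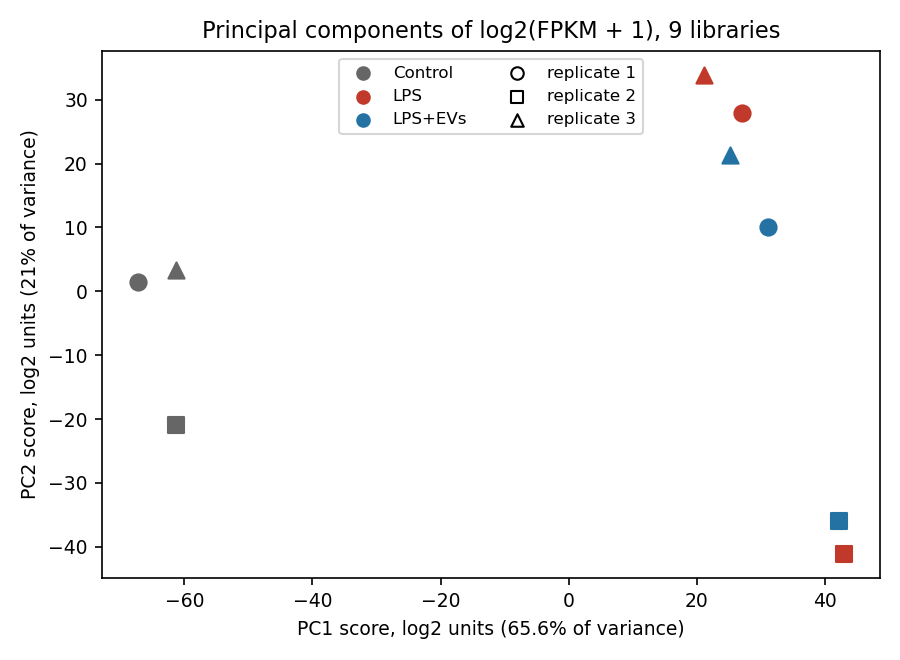
Scores of the 9 libraries on the first (horizontal) and second (vertical) principal component of log2(FPKM + 1), in log2 units, with color for the group and shape for the replicate number. The 3 Control libraries lie between -67.3 and -61.3 on the first component and the 6 LPS-treated libraries between 21.1 and 43.1.

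The comparison of LPS with Control asks what the endotoxin, with the unnamed agent if it was given, did to these cells before EVs enter the picture. Nos2, the inducible nitric oxide synthase, rose from 3.01 ± 0.222 FPKM in Control to 1310 ± 345 FPKM in LPS (mean ± SD, n = 3 each), a log2 fold change of 8.33 (SE 0.23, adjusted p = 7.6e-07). Il1b, which encodes the inflammatory cytokine interleukin-1 beta, rose from 60.8 ± 9.89 to 2890 ± 1250 FPKM (log2 5.48, SE 0.31, adjusted p = 7.05e-06). Genes of cell division went the other way: Ube2c, a ubiquitin-conjugating enzyme needed to leave mitosis, fell from 55.8 ± 5.39 to 0.798 ± 0.388 FPKM (log2 -5.00, SE 0.22, adjusted p = 2.52e-06). Kif20a, Racgap1, Top2a, Ccna2 and Ccnb2, which all serve mitosis, DNA replication or cytokinesis, fell with log2 changes from -4.75 to -4.65 (adjusted p of 1.58e-06 or less for each). Log2 changes in this report are differences of log2(FPKM + 1), which understate the fold change of genes near 0 FPKM, as these were in LPS. The other large rises were Il12b, a subunit of interleukin-12 (log2 6.12, SE 0.87, adjusted p = 0.000926), Csf2, which encodes GM-CSF (6.06, SE 0.46), the neutrophil-attracting chemokine Cxcl1 (5.20, SE 0.29) and Ptges, a prostaglandin E synthase (5.16, SE 0.51). Il12b varied widely within LPS, at 124 ± 132 FPKM against 0.213 ± 0.144 FPKM in Control.

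Inflammatory mediators rose together. In the list of inflammatory cytokines 16 of 22 tested genes rose and 1 fell, with the same counts adjusted over the list alone, among them Il1a (log2 4.50), Ebi3 (4.10) and Inhba (3.69). As a list the cytokines were higher than other genes (camera adjusted p = 8.83e-11, adjusted p = 0.018 with an estimated correlation). Il6 rose to 157 ± 17 FPKM from 4.83 ± 4.06 FPKM (log2 5.03, SE 0.49, adjusted p = 0.000132). Tnf stood at 22.2 ± 6.08 FPKM against 18.5 ± 6.48 FPKM (log2 0.27, 95% interval -0.47 to 1.01, adjusted p = 0.526, 0.014 with the replicate block and median-of-ratios scaling, range over its alternatives 0.014 to 0.889). Il10, an anti-inflammatory cytokine listed at 0 in 2 of the 3 Control libraries, rose to 3.43 ± 2.46 FPKM (adjusted p = 0.00727). Chemokine genes behaved alike, with 15 of 24 rising and 1 falling (the same adjusted over the list alone), led by Cxcl2 (log2 4.62), Cxcl1, Ccl3 (3.07) and Cxcl3 (3.85). For chemokines camera gave an adjusted p of 7.1e-08 (adjusted p = 0.0554 with an estimated correlation). Interferon-stimulated genes, the antiviral program, rose in 33 of 49 cases and fell in none (37 rose adjusted over the list alone), for example Usp18 (log2 2.57), Isg20 (1.47), Ifit3 (4.80) and Gbp4 (2.07). The camera adjusted p of these interferon-stimulated genes was 6.57e-16 (adjusted p = 0.227 with an estimated correlation). In the NF-kB and Toll-like receptor list 20 of 35 genes rose and 6 fell (21 and 6 adjusted over the list alone), with rises of Irak2 (log2 1.77), Birc2 (2.01), Tnip1 (1.29) and Nfkbia (2.20). The NF-kB list had a camera adjusted p of 3.88e-07 (adjusted p = 0.0712 with an estimated correlation).

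Genes of dendritic cell maturation also rose. That list had 13 risen and 1 fallen of 22 genes (the same adjusted over the list alone), with the checkpoint ligand Cd274 (log2 3.02), Cd200 (2.54), Il2ra (3.59) and Slamf1 (3.12) foremost. As a list the maturation genes had a camera adjusted p of 7.1e-08 (adjusted p = 0.14 with an estimated correlation). The costimulatory genes Cd40 and Cd80 rose with log2 changes of 2.31 (SE 0.35, adjusted p = 0.00128) and 1.49 (SE 0.29, adjusted p = 0.00448), and the lymph node homing receptor Ccr7 with 1.56 (SE 0.47, adjusted p = 0.0288). Cd86 did not pass, at a log2 difference of 0.84 (SE 0.36, adjusted p = 0.0938), but passed with the replicate number as a block (adjusted p = 0.00647, range over its alternatives 0.00136 to 0.277). The Ccr7 call ended without Control replicate 1, Control replicate 2 or LPS replicate 3 (adjusted p = 0.101, 0.0747 and 0.0628, range over its alternatives 0.000284 to 0.101). Genes of MHC class I presentation had 6 risen and 4 fallen of 21 (7 and 4 adjusted over the list alone), with Nlrc5 (log2 1.48) and B2m (0.96) up and RT1-T24-1 (-1.72) and Canx (-0.56) down. Camera placed that list higher (adjusted p = 0.0169, adjusted p = 0.297 with an estimated correlation, and 0.0532 without LPS replicate 2). Genes of MHC class II presentation had 2 risen and 5 fallen of 15 (the same adjusted over the list alone), with Ifi30 (log2 -2.28), RT1-DMa (-2.46) and RT1-DMb (-2.77) down and the protease Ctsb (0.90) up. The class II list as a whole did not pass (adjusted p = 0.63), but passed as lower with the replicate block and median-of-ratios scaling (0.0268) and with libraries numbered 1 and 3 alone (0.041, range over its alternatives 0.0268 to 0.999). Regulatory and tolerance genes had 11 risen and 4 fallen of 28 (11 and 5 adjusted over the list alone), with Tnfaip3 (log2 1.90) and Hmox1 (2.67) up and the receptor Axl (-2.11) down. Camera gave the regulatory genes an adjusted p of 0.00601 (adjusted p = 0.0735 with an estimated correlation). Alternative macrophage activation had 2 risen and 9 fallen of 16 (3 and 9 adjusted over the list alone), with the mannose receptor Mrc1 (log2 -3.98), Clec10a (-3.31) and Folr2 (-1.94) down and Arg1 (2.97) up. That list did not pass (adjusted p = 0.143) except with the replicate block (0.0479, and 0.204 with the block and an estimated correlation) and some further alternatives (range 0.0117 to 0.458).

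**Figure D2:**
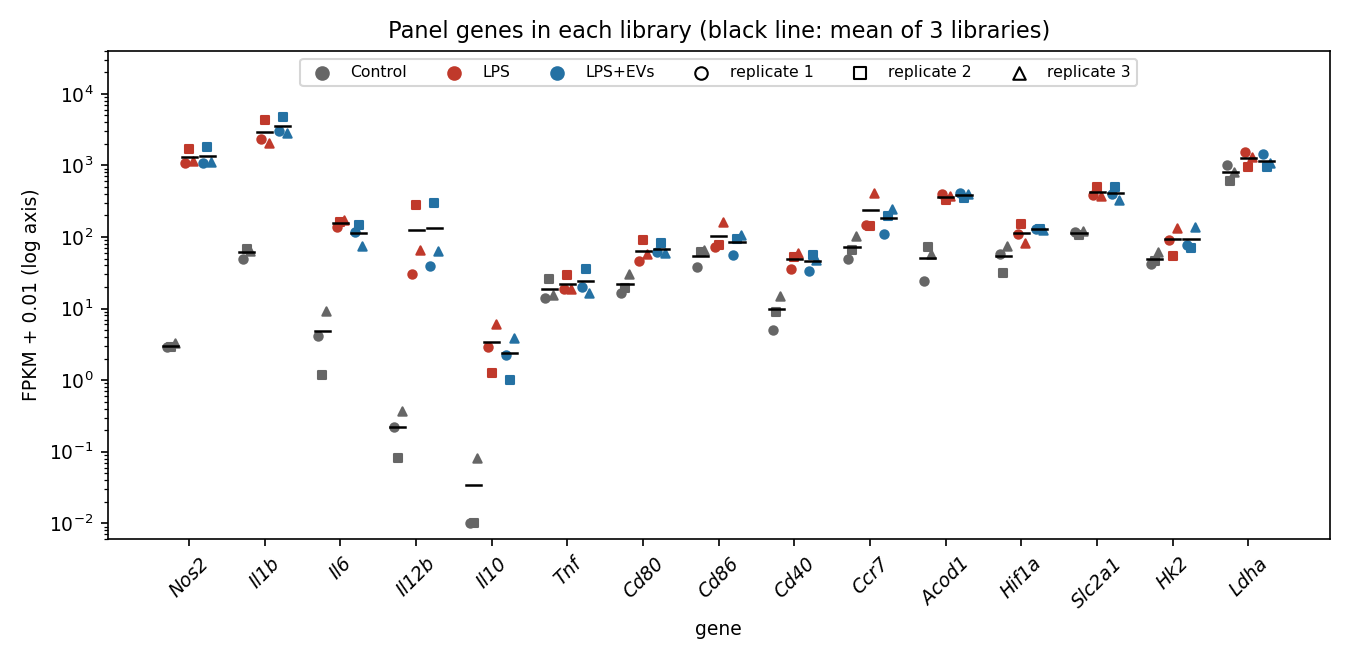
FPKM + 0.01 (vertical, log axis) of 15 genes of the fixed panel (horizontal) in each of the 9 libraries, with color for the group, shape for the replicate number and a black line at the mean of 3 libraries. Nos2 means were 3.01 FPKM in Control, 1310 FPKM in LPS and 1330 FPKM in LPS+EVs.

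Metabolic genes divided. LPS-linked immunometabolism, a list of genes for nitric oxide, itaconate and prostaglandin synthesis, had 11 risen and 2 fallen of 17 (12 and 2 adjusted over the list alone), with Nos2, Ptges, Ass1 (log2 3.57) and Slc7a2 (2.89) foremost. Acod1, which makes itaconate, rose by log2 2.93 (SE 0.33, adjusted p = 0.000302). Camera gave that list an adjusted p of 3.02e-07 (adjusted p = 0.0237 with an estimated correlation). Glycolysis genes rose in 12 of 25 cases and fell in none (the same adjusted over the list alone), with Eno2 (log2 2.40), the glucose transporter Slc2a1 (1.85), the lactate exporter Slc16a3 (1.81) and Pfkfb3 (1.54) foremost. Glycolysis as a list had a camera adjusted p of 8.21e-08 (adjusted p = 0.14 with an estimated correlation). Hk2 (log2 0.80, adjusted p = 0.0946) and Ldha (0.66, adjusted p = 0.0619) did not pass, though both did with the replicate block (adjusted p = 0.00635 and 0.00166, ranges over their alternatives 0.000995 to 0.26 and 0.000836 to 0.191). Hk2 also passed without LPS replicate 2 (adjusted p = 0.0199), and Ldha without Control replicate 1 (0.0476) or LPS replicate 2 (0.0261). Hypoxia response genes rose in 13 of 18 cases and fell in none (14 rose adjusted over the list alone), with Adm (log2 2.96), Kdm3a (1.10) and Ndrg1 (1.69). Hypoxia genes had a camera adjusted p of 2.94e-08 (adjusted p = 0.196 with an estimated correlation). Hif1a, their transcription factor, rose by log2 1.10 (SE 0.31, adjusted p = 0.0215), a call that ended without LPS replicate 1 or LPS replicate 2 (adjusted p = 0.0526 and 0.0562, range 0.0142 to 0.0562).

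Many nuclear genes of mitochondrial proteins fell. Among nuclear genes of oxidative phosphorylation 57 of 79 fell and none rose (65 fell and 2 rose adjusted over the list alone), including the ATP synthase genes Atp5f1a (log2 -1.31), Atp5f1b (-1.28), Atp5po (-1.12) and Atp5mc3 (-1.26). As a list they had a camera adjusted p of 1.63e-09 (adjusted p = 0.227 with an estimated correlation). In the tricarboxylic acid cycle 19 of 30 genes fell and none rose (20 fell adjusted over the list alone), with Mdh2 (log2 -1.21), Sdha (-0.90) and Idh2 (-1.96). The cycle genes had a camera adjusted p of 0.00139 (adjusted p = 0.227 with an estimated correlation). In the mitochondrial ribosome and protein import list 29 of 39 fell and none rose (31 fell adjusted over the list alone), with Hspe1 (log2 -1.53) and Timm50 (-1.19). Mitochondrial ribosome and import genes had a camera adjusted p of 8.67e-06 (adjusted p = 0.427 with an estimated correlation). Of 13 mitochondrially encoded genes 5 fell and none rose (5 adjusted over the list alone), among them ND1 (log2 -1.10), ND6 (-1.89) and ND4 (-1.44). That list did not pass (adjusted p = 0.286). Fasn, the fatty acid synthase, fell by log2 -3.50 and the lipase Lpl by log2 -2.10. Fatty acid synthesis and lipid storage as a list (3 rose and 6 fell of 19, 4 and 7 adjusted over the list alone) did not pass (adjusted p = 0.297). Nor did fatty acid oxidation (1 rose and 10 fell of 23, the same adjusted over the list alone, adjusted p = 0.108, 0.0412 without Control replicate 3 and 0.0144 without a filter, range over its alternatives 0.0144 to 0.427) or cholesterol synthesis (1 rose and 7 fell of 22, the same adjusted over the list alone, 0.264, 0.0423 without a filter and 0.0325 with libraries numbered 1 and 3 alone, range 0.0325 to 0.747). The pentose phosphate pathway (1 rose and 4 fell of 9, the same adjusted over the list alone, 0.361) and mitochondrial dynamics, mitophagy and biogenesis (1 rose and 9 fell of 29, the same adjusted over the list alone, 0.636) did not pass either. Ppargc1a, a regulator of mitochondrial biogenesis, was too low to test, with a mean of 0.0148 FPKM or less in every group.

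Proliferation genes fell almost throughout. In the cell cycle list 34 of 36 genes fell and none rose (35 fell adjusted over the list alone), with Cdc20 (log2 -4.43), Top2a (-4.68), Ccna2 (-4.67) and Cenpf (-3.44) foremost. The cell cycle median was -3.27, with a camera adjusted p of 2.34e-22 (adjusted p = 0.0333 with an estimated correlation). Apoptosis and p53 target genes had 11 risen and 1 fallen of 22 (12 and 1 adjusted over the list alone), with Mdm2 (log2 2.01) and the cell cycle inhibitor Cdkn1a (2.39) up and Bcl2 (-1.54) down. For p53 targets camera gave an adjusted p of 1.05e-06 (adjusted p = 0.0333 with an estimated correlation). Antioxidant and NRF2 target genes had 11 risen and 1 fallen of 23 (12 and 3 adjusted over the list alone), with the ferritin chain Fth1 (log2 2.27), Hmox1 (2.67), Txnrd1 (1.14) and Prdx1 (1.48) up. For antioxidant genes camera gave an adjusted p of 3.78e-05 (adjusted p = 0.227 with an estimated correlation). Fth1 alone took 2.47 ± 0.546% of assigned reads in LPS and 0.503 ± 0.04% in Control (n = 3 each), and its call ended without a filter (adjusted p = 0.0936). Immediate early genes had 7 risen and 1 fallen of 16 (the same adjusted over the list alone), with Dusp2 (log2 3.12) and Dusp1 (1.95) up and Egr2 (-1.85) down. For immediate early genes camera gave an adjusted p of 0.000563 (adjusted p = 0.227 with an estimated correlation). Matrix metalloproteinases and bone-related genes had 4 risen and 1 fallen of 17 (3 and 1 adjusted over the list alone), with the proteinase Adamts4 (log2 1.06) and its class of inhibitor Timp1 (1.25) up and Ocstamp (-1.56), a gene of osteoclast fusion, down. Camera gave that list an adjusted p of 0.0169 (adjusted p = 0.484 with an estimated correlation, and 0.0626 without LPS replicate 1). Inflammasome and pyroptosis genes (4 rose and 2 fell of 13, the same adjusted over the list alone, adjusted p = 0.0912) and lysosome genes (7 rose and 4 fell of 29, the same adjusted over the list alone, 0.0768) did not pass. Nor did endoplasmic reticulum stress and amino acid response (3 rose and 8 fell of 20, the same adjusted over the list alone, 0.691) or heat shock genes (2 rose and 1 fell of 10, 1 and 1 adjusted over the list alone, 0.208). Leaving out LPS replicate 3 brought inflammasome and lysosome genes to adjusted p of 0.0472 and 0.0453 (ranges over their alternatives 0.0472 to 0.289 and 0.0453 to 0.45).

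Some markers of cell types changed, and no marker list passed as a whole, though 2 did under some alternatives. Macrophage and monocyte markers had 2 risen and 10 fallen of 18 (the same adjusted over the list alone, camera adjusted p = 0.143), with Mrc1, Ccr2 (log2 -2.73) and Fcgr1a (-0.89) down and Cd14 (1.26), the LPS coreceptor, up. The macrophage and monocyte list passed as lower without a filter (0.0167), with the replicate block and median-of-ratios scaling (0.035) and with libraries numbered 1 and 3 alone (0.0236, range over its alternatives 0.0167 to 0.469). Dendritic cell markers had 1 risen and 5 fallen of 13 (the same adjusted over the list alone, adjusted p = 0.63), with Sirpa (log2 -0.85) and Cd1d1 (-0.85) down. Neutrophil and granulocyte precursor markers had 1 risen and 4 fallen of 7 (1 and 6 adjusted over the list alone, adjusted p = 0.221, 0.0466 without Control replicate 2, range over its alternatives 0.0466 to 0.608), with Cxcr2 (log2 -3.92) down and Lcn2 (4.65) up. Stromal and mesenchymal markers had 1 risen and 2 fallen of 25 (0 and 1 adjusted over the list alone), with a median of -0.08, a mean of -0.16 and a camera direction of up (adjusted p = 0.466). Hba-a2, an alpha globin of red cells, stood at 199 ± 207 FPKM in Control and was lower in LPS (log2 -4.42, adjusted p = 0.00132). Itga2b, an integrin of megakaryocytes, rose (log2 1.40). Of 4 erythroid and megakaryocyte markers 2 rose and 2 fell (the same adjusted over the list alone). With too few tested genes for camera, mast cell, basophil and eosinophil markers had 2 risen and none fallen of 3, T and NK cell markers 1 risen and 2 fallen of 4 (2 and 2 adjusted over the list alone), and B and plasma cell markers none risen and 1 fallen of 2. The counts for the mast cell and B cell groups were the same adjusted over the list alone.

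By limma, 1368 of 11141 tested genes were higher and 3201 lower in LPS than in Control at an adjusted p under 0.05, and 548 and 1406 of them differed by at least 2-fold. The groups did not overlap for 55.1% of tested genes, where chance gives 10%. The median log2 change of all tested genes was -0.19 as deposited and 0.01 after median-of-ratios scaling. The split between directions depended on this: 29.9% of changed genes were higher as deposited and 47.4% (2041 higher and 2265 lower) after that scaling. Camera called 14 of 34 tested lists higher and 4 lower, of which 3 and 1 held with an estimated correlation. With the replicate block and an estimated correlation none of them passed (cytokines 0.077, immunometabolism 0.103, p53 targets 0.108, cell cycle 0.108). Each of the 18 kept its direction and its call after median-of-ratios scaling.

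The comparison of LPS+EVs with LPS asks what the vesicles added, which the series title ties to delivery of mitochondria and to dendritic cell metabolism. No single gene passed the test, the inflammatory genes of the panel included. Nos2 was at 1330 ± 404 FPKM with EVs and 1310 ± 345 FPKM without (n = 3 each, log2 difference 0.01, 95% interval -0.51 to 0.54, adjusted p = 0.999). Il1b was at 3500 ± 1020 and 2890 ± 1250 FPKM (log2 0.32, interval -0.37 to 1.02), Il6 at 112 ± 35.9 and 157 ± 17 FPKM (-0.53, interval -1.65 to 0.59) and Il10 at 2.37 ± 1.45 and 3.43 ± 2.46 FPKM (-0.34, interval -1.31 to 0.64). The maturation genes Cd40 (log2 -0.11, interval -0.91 to 0.69), Cd80 (0.12, interval -0.55 to 0.79), Cd86 (-0.23, interval -1.05 to 0.59) and Ccr7 (-0.24, interval -1.33 to 0.84) did not pass either. Among metabolic genes of the panel other than Nos2, Slc2a1 was the most tightly bounded (log2 -0.05, interval -0.43 to 0.34), followed in width by Ldha (-0.13, interval -0.70 to 0.43), Hif1a (0.20, interval -0.51 to 0.90), Acod1 (0.09, interval -0.67 to 0.85) and Hk2 (0.07, interval -0.72 to 0.85). Tnf (log2 0.07, interval -0.67 to 0.81) and Il12b (0.13, interval -1.84 to 2.11) did not pass, and all 15 tested panel genes had an adjusted p of 0.999. All these intervals come from the fit without the replicate block, so they include differences between replicate numbers. LPS and LPS+EVs libraries of 1 number correlated at 0.65, 0.86 and 0.69. With the block no panel gene passed either (adjusted p from 0.776 to 0.996). Il1b and Acod1 were higher with EVs in each same-number pair, and Il6 and Il10 lower. The other tested panel genes went both ways. From 3 pairs an exact p cannot fall below 0.25.

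Of the tested lists, 2 were called between LPS+EVs and LPS with the preset correlation, and none with an estimated correlation. Mitochondrially encoded genes, all of them parts of the respiratory chain or ATP synthase, were lower with EVs, with 12 of 13 below 0 and a median log2 of -0.60. Their camera adjusted p was 1.93e-11 (adjusted p = 0.316 with an estimated correlation and 0.72 with that and the replicate block, other alternatives from 8.06e-19 to 0.000159). None fell in the test over all genes, and 4 fell adjusted over the list alone. ND4L, a subunit of complex I, was at 10.8 ± 11.5 FPKM with EVs and 91.7 ± 35.0 FPKM without (log2 -3.39, SE 0.66). ND3 stood at 60.7 ± 28.7 and 207 ± 82.3 FPKM (log2 -1.80, SE 0.45), and ND4 at 168 ± 40.2 and 402 ± 195 FPKM (log2 -1.15, SE 0.35). ND4L shares bases with ND4 in the mitochondrial genome, as does ATP8 with ATP6, so their reads are hard to assign. COX1, in contrast, was at 11660 ± 2656 and 11460 ± 2455 FPKM (log2 0.02, SE 0.22). As a share of reads, the 7 ND genes held 0.557 ± 0.1% in Control, 0.289 ± 0.078% in LPS and 0.169 ± 0.036% in LPS+EVs. That share was lower with EVs in 3 of 3 pairs of libraries with 1 replicate number. The share of all 13 mitochondrially encoded genes was 3.203 ± 0.415% in Control, 3.25 ± 0.478% in LPS and 2.91 ± 0.649% in LPS+EVs, and with EVs it was higher in pair 1 (3.61% against 3.15%) and lower in pairs 2 (2.78% against 3.77%) and 3 (2.33% against 2.83%).

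**Figure D3:**
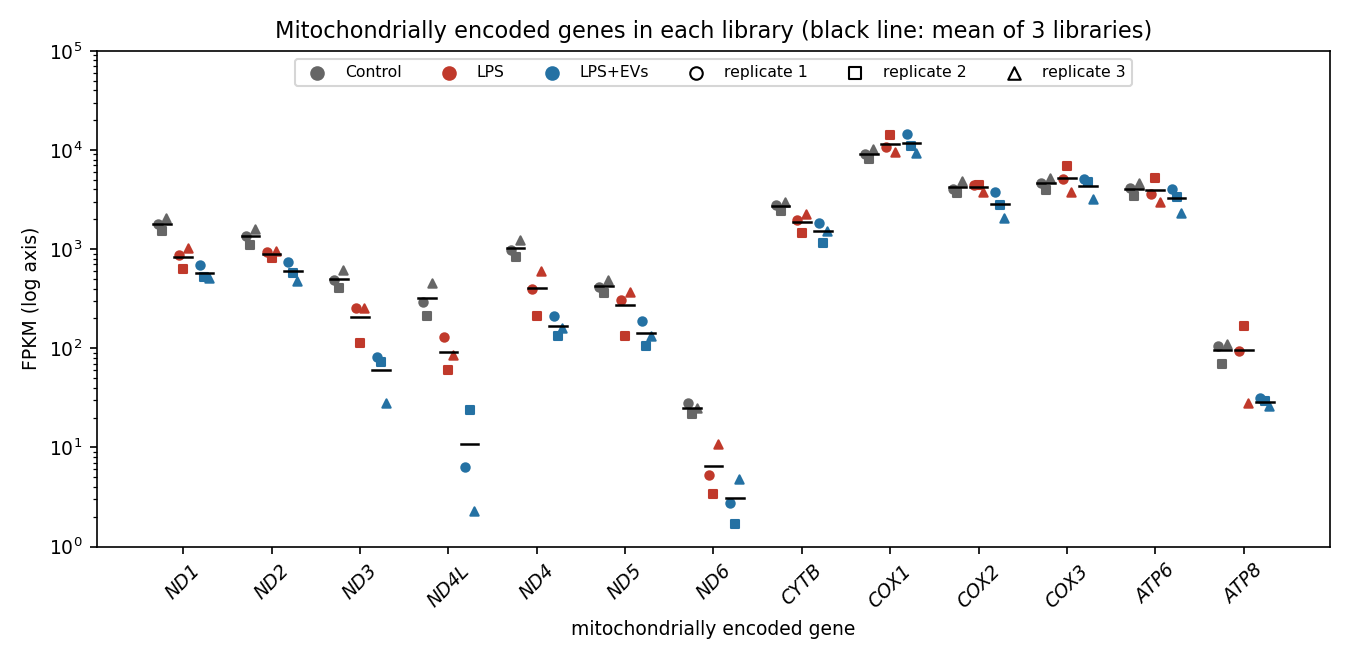
FPKM (vertical, log axis) of the 13 mitochondrially encoded genes (horizontal) in each of the 9 libraries, with color for the group, shape for the replicate number and a black line at the mean of 3 libraries. ND3 means were 500 FPKM in Control, 207 FPKM in LPS and 60.7 FPKM in LPS+EVs, and COX1 means 9104, 11460 and 11660 FPKM.

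Nuclear genes of oxidative phosphorylation were slightly higher with EVs, with 66 of 79 above 0 and a median log2 of 0.12. A gene length effect is not excluded. The 375 nuclear genes with models of at most 700 bases had the same median (0.12, 270 or 72% above 0). That set did not leave out oxidative phosphorylation or ribosomal protein genes, so the match is no independent sign of a length effect. For the oxidative phosphorylation list the camera adjusted p was 1.23e-07 (adjusted p = 0.947 with an estimated correlation). None of them passed over all genes or adjusted over the list alone, and the largest by rank were Ndufb7 (log2 0.35), Ndufa8 (0.24), Cycs (-0.21) and Atp5mc2 (0.29). With the replicate number as a block, MHC class II presentation also came out higher (13 of 15 above 0, median 0.23, adjusted p = 0.000766, adjusted p = 0.821 with the block and an estimated correlation, range over its alternatives 0.000766 to 0.947). Hypoxia response came out lower (16 of 18 below 0, median -0.14, adjusted p = 0.0183, adjusted p = 0.821 with the block and an estimated correlation, range 0.00854 to 0.947). Without the block these lists had adjusted p of 0.291 and 0.27, but 0.0111 for MHC class II without LPS replicate 2 and 0.00854 for hypoxia without LPS+EVs replicate 1. Class II genes were higher in number 2 than in the mean of 1 and 3 (list median log2 1.39 in LPS and 1.04 in LPS+EVs). Leaving out LPS replicate 2 alone therefore raises their difference by itself. With number 2 left out of both groups, a setting chosen after seeing the data, class II genes still passed as higher (0.00487). Hypoxia genes passed as lower in that setting (0.0454). With the block and median-of-ratios scaling, class II had an adjusted p of 0.00271 and hypoxia of 0.0262. Inflammatory cytokines (median log2 -0.01, adjusted p = 0.519), chemokines (-0.13, 0.566), interferon-stimulated genes (-0.11, 0.344), glycolysis (-0.05, 0.916), the tricarboxylic acid cycle (0.03, 0.27) and the cell cycle list (0.07, 0.532) did not pass. Interferon-stimulated genes passed as lower without LPS replicate 1 (0.00393), LPS replicate 3 (0.0292) or LPS+EVs replicate 2 (3.76e-07, range over their alternatives 3.76e-07 to 0.947). In all 3 groups 40 of these 49 genes were higher in the library numbered 2. Each of these omissions gives number 2 more weight in LPS than in LPS+EVs, which by itself lowers the difference. Cytokines passed as lower without LPS+EVs replicate 2 (0.00808, range 0.00808 to 0.947), and the cell cycle list as higher without LPS replicate 2 (0.0406, range 0.0406 to 0.954). Heat shock genes passed as lower without LPS replicate 1 (0.0176), LPS replicate 3 (0.0292) or LPS+EVs replicate 2 (3.99e-05, range 3.99e-05 to 0.947). Stromal markers passed as higher without LPS replicate 1 (0.00137) or LPS+EVs replicate 2 (9.2e-05, range 9.2e-05 to 0.947), and lysosome genes as higher without LPS replicate 1 (0.0193, range 0.0193 to 0.947). Of the stromal markers 24 of 25 were lower in the library numbered 2 in all 3 groups. More weight on number 2 in LPS than in LPS+EVs therefore raises their difference by itself. Macrophage and monocyte markers passed as higher without LPS replicate 2 (0.0237, range 0.0237 to 0.947) or LPS+EVs replicate 3 (0.0347). Dendritic cell maturation (median -0.02) and mitochondrial ribosome and import genes (-0.01) had medians and means below 0 but a camera direction of up (adjusted p = 0.84 and 0.835). Medians of the 30 tested lists without a call here lay between -0.13 and 0.46, the highest being neutrophil markers (5 of 7 above 0, adjusted p = 0.472).

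**Figure D4:**
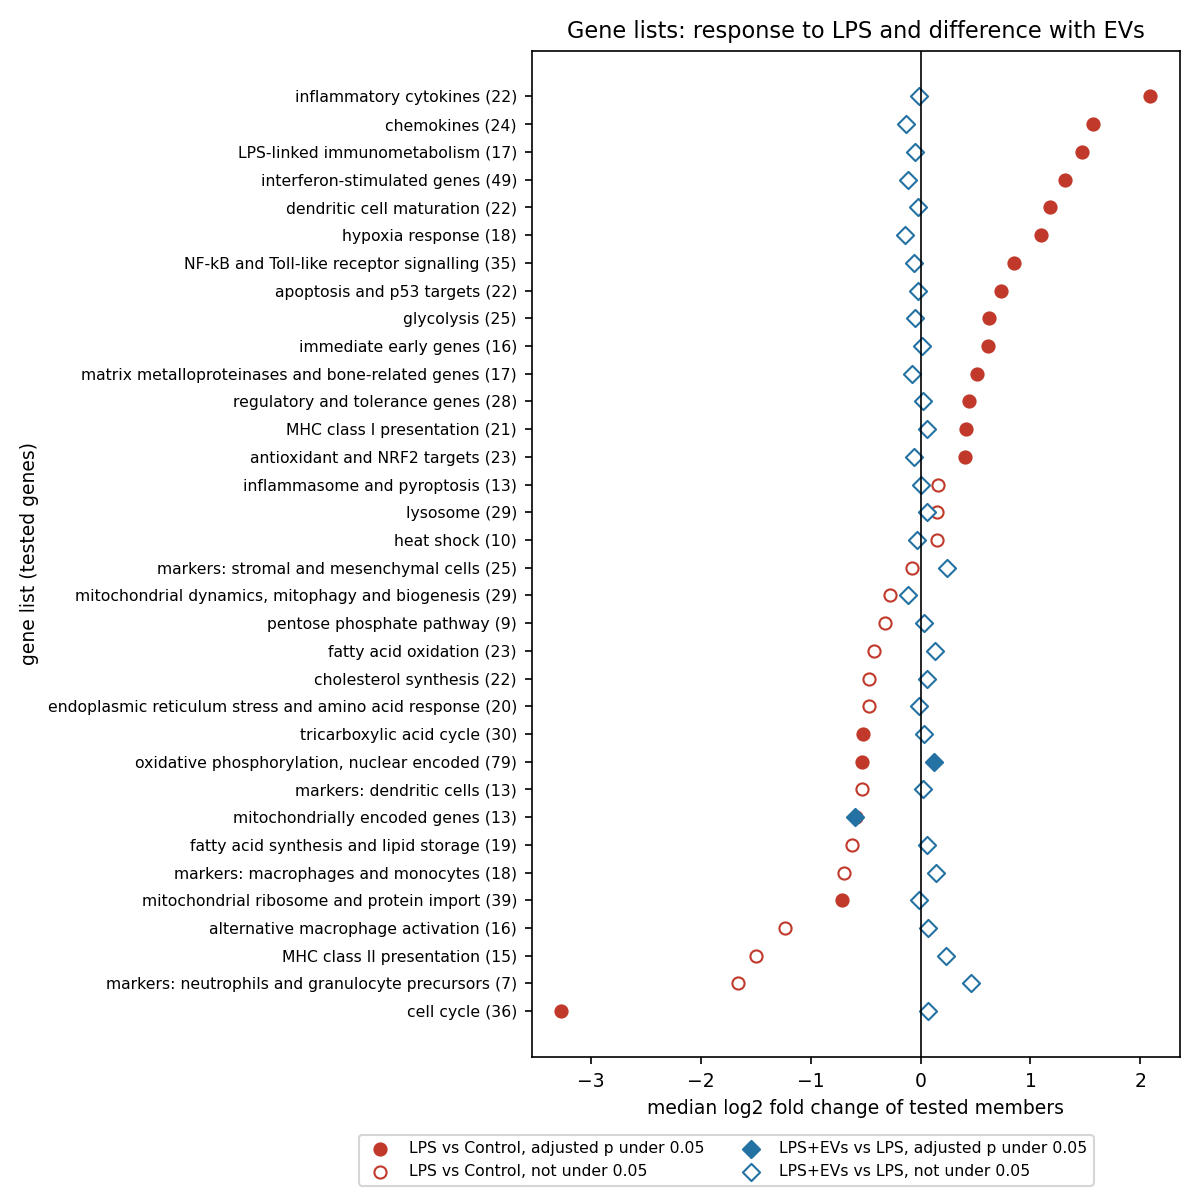
Median log2 fold change of the tested members (horizontal) of 34 gene lists (vertical, with the number of tested genes) for LPS vs Control (circles) and LPS+EVs vs LPS (diamonds), filled where the camera adjusted p with the preset correlation was under 0.05. Medians for LPS vs Control run from -3.27 to 2.09, and the 2 filled diamonds are mitochondrially encoded genes at -0.60 and nuclear oxidative phosphorylation genes at 0.12.

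Limma called 0 of 11141 genes at an adjusted p under 0.05 in either direction, with 295 genes at an unadjusted p under 0.05 where chance gives 557 for unpaired libraries, and limma-voom called 0 with 277. The blocked model called 0 as well, with 600 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.776. The count at an unadjusted p under 0.05 depended on single libraries, with 1886 genes without LPS replicate 2 (1 gene called, adjusted p = 0.0417), 81 without LPS replicate 3 and 80 without LPS+EVs replicate 3. Libraries numbered 1 and 3 alone gave 1556 such genes and 0 called (lowest adjusted p 0.0893). The groups did not overlap for 6.6% of genes, where chance gives 10% for unpaired libraries and can give less where the replicate numbers pair them. For 85.8% of genes the 95% interval of the difference in log2(FPKM + 1) lay between -1 and 1 (95% of genes with the block). Because 1 is added, genes of low FPKM can change by more than 2-fold within these limits, so their fold change is not bounded. In simulated data of this size limma found 40.1% of 2-fold and 83.8% of 4-fold changes. The libraries of that simulation were independent, unlike the same-number libraries here, so these shares need not hold for the real comparison. With replicate differences simulated and the block fitted, the shares were 68.5% and 96.7%. List calls moved with single libraries, from 1 higher list to 4 without LPS replicate 2 and 3 without LPS replicate 1, and from 1 lower list to 4 without LPS+EVs replicate 2 and 3 without LPS replicate 1 or 3. Leaving out LPS+EVs replicate 1 gave 2 lower lists, and leaving out LPS+EVs replicate 2 or 3 gave 2 higher lists.

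Whether EVs moved the LPS response back toward Control was asked of the genes that LPS had changed. Genes raised by LPS had a median log2 change of 0.85 over Control with LPS and 0.86 with LPS+EVs, and genes lowered by LPS had medians of -0.92 and -0.93. Of the 1368 raised genes 658 were lower with EVs than without (median difference 0.008), and of the 3201 lowered genes 1614 were higher (median 0.002). None of the 4569 genes passed the test for LPS+EVs against LPS in the opposite or in the same direction, as followed from the count of 0. For 4105 of them (89.8%) the 95% interval of that difference in log2(FPKM + 1) lay between -1 and 1. This does not bound the fold change of genes with low FPKM, among them genes lowered by LPS such as Ube2c (0.798 FPKM in LPS). Both comparisons use the LPS libraries with opposite sign, which in simulated groups without any effect, of LPS or of EVs, gave a correlation of -0.50 between their log2 changes across genes. The measured correlation was -0.06. It cannot be set against the simulated one, because the real LPS changes, absent from the simulation, draw a correlation toward 0. The covariance was -0.0116 against -0.0366 in the simulation and -0.0163 in a simulation with the spread of the blocked model. Genes are not independent replicates.

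The comparison of LPS+EVs with Control shows the response to LPS in the presence of EVs. Nos2 rose to 1330 ± 404 FPKM from 3.01 ± 0.222 FPKM (n = 3 each, log2 8.34, SE 0.23, adjusted p = 8.73e-07), Il12b by log2 6.25 (SE 0.87, adjusted p = 0.000826), Csf2 by 6.16 (SE 0.46, adjusted p = 3.19e-05) and Il1b by 5.80 (SE 0.31, adjusted p = 5.14e-06). ND4L fell from 318 ± 125 FPKM in Control to 10.8 ± 11.5 FPKM (log2 -5.17, SE 0.66, adjusted p = 0.000534). Ube2c (log2 -4.98, SE 0.22), Ccna2 (-4.85, SE 0.16) and the globin gene Hba-a2 (-4.77, SE 0.68) fell nearly as far. In the panel Il6 (log2 4.50), Il10 (1.62), Cd80 (1.61), Cd40 (2.20), Acod1 (3.02), Hif1a (1.30) and Slc2a1 (1.80) rose. Tnf (log2 0.34, adjusted p = 0.423), Cd86 (0.61, 0.202), Ccr7 (1.32, 0.0504), Hk2 (0.87, 0.0699) and Ldha (0.53, 0.117) did not pass. With the replicate block all 5 passed (adjusted p = 0.0448, 0.0237, 0.00136, 0.00406 and 0.00429, with ranges over their alternatives of 0.00665 to 0.939, 0.00363 to 0.5, 0.0005 to 0.158, 0.000644 to 0.21 and 0.00152 to 0.328). Ccr7 also passed without Control replicate 3 (adjusted p = 0.0478), LPS replicate 2 (0.0403), LPS replicate 3 (0.0175) or LPS+EVs replicate 1 (0.0372), and Hk2 without LPS replicate 2 (0.0276) or LPS replicate 3 (0.0461).

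Inflammatory cytokines had 15 risen and 1 fallen of 22 (17 and 1 adjusted over the list alone, camera adjusted p = 3.55e-10, adjusted p = 0.0212 with an estimated correlation). The cell cycle list had 34 fallen of 36 (34 adjusted over the list alone, adjusted p = 4.06e-21, adjusted p = 0.0383 with an estimated correlation). LPS-linked immunometabolism (11 risen and 1 fallen of 17, 11 and 2 adjusted over the list alone, adjusted p = 2.59e-06) and apoptosis and p53 targets (11 and 1 of 22, the same adjusted over the list alone, 5.08e-06) also kept their calls with an estimated correlation (adjusted p = 0.0344 and 0.0447). With the replicate block and an estimated correlation none of these 4 lists passed (cytokines 0.0869, cell cycle 0.108, immunometabolism 0.108, p53 targets 0.109). Mitochondrially encoded genes had 9 fallen of 13 (10 adjusted over the list alone), with ND1 (log2 -1.64), ND4 (-2.60) and ND6 (-2.72) beside ND4L. Their list median was -1.58, with a camera adjusted p of 0.00873 (adjusted p = 0.344 with an estimated correlation). Nuclear oxidative phosphorylation genes had 3 risen and 47 fallen of 79 (the same adjusted over the list alone, adjusted p = 2.92e-06, adjusted p = 0.344 with an estimated correlation). Lysosome genes had 8 risen and 4 fallen of 29 (the same adjusted over the list alone), with Gla (log2 1.61) and Ctsb (0.89) up and Gusb (-1.85) and Hexa (-0.89) down. For lysosome genes camera gave an adjusted p of 0.0279 (adjusted p = 0.344 with an estimated correlation, and 0.0798 without a filter). Matrix metalloproteinases and bone-related genes had 3 risen and 1 fallen of 17 (the same adjusted over the list alone, adjusted p = 0.0401, adjusted p = 0.585 with an estimated correlation). That call also ended without Control replicate 2 (0.0769), LPS+EVs replicate 1 (0.107) or LPS+EVs replicate 3 (0.0552) and after median-of-ratios scaling (0.0594). Heat shock genes had a median of -0.06 but a mean of 0.42 and a camera direction of up (adjusted p = 0.493).

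By limma 1505 genes were higher and 3436 lower in LPS+EVs than in Control, 588 and 1537 of them by at least 2-fold, and the groups did not overlap for 60.2% of genes, where chance gives 10%. Changed genes were higher in 30.5% of cases as deposited and in 47.8% (2244 higher and 2454 lower) after median-of-ratios scaling, which moved the median of all genes from -0.19 to 0.01. Camera called 15 lists higher and 5 lower, of which 3 and 1 held with an estimated correlation.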

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

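Chosen only after the results were seen were the tests with TMM scaling, limma-voom, the replicate block with median-of-ratios scaling, and libraries numbered 1 and 3 alone. No named gene or list that had passed reversed under any alternative. Direction was compared only for results that had passed, and for the others only the side of the threshold. Of 8965 alternative values for named genes 8761 kept their side of the threshold, 133 lost and 71 gained the call. Of 2040 for lists 1956 kept their side, 43 lost and 41 gained the call. For named genes, and for lists with the preset correlation, the replicate block changed no call beyond those given in the report and gains for Mcpt2, Gzmb and Col3a1 (LPS vs Control) and Mcpt2, Col6a2 and Cxcl12 (LPS+EVs vs Control). An estimated correlation left 3 higher and 1 lower list for LPS vs Control and 0 and 0 for LPS+EVs vs LPS. For LPS+EVs vs Control it left 3 and 1. A correlation above the preset 0.01 is argued against as the whole cause. In LPS vs Control it was estimated at 0.012 for cytokines, 0.004 for immunometabolism and -0.019 for regulatory genes. Their unadjusted camera p still rose from 7.79e-12 to 0.00053, 8e-08 to 0.00139 and 0.00283 to 0.0151. Other lists had higher estimates, such as 0.568 for interferon-stimulated genes. What else weakened the calls was not tested. The replicate block with an estimated correlation left none in any comparison. A 2-fold threshold, which keeps fewer genes by construction, left 548 higher and 1406 lower genes for LPS vs Control and 588 and 1537 for LPS+EVs vs Control. Without a filter 8 lists were lower for LPS vs Control. For LPS+EVs vs LPS, 2 lists were higher and 2 lower with the replicate block, with that block and median-of-ratios scaling, and with libraries numbered 1 and 3 alone. The latter settings each gave 7 lower lists for LPS vs Control, and the block with median-of-ratios scaling gave 2754 higher genes for LPS vs Control and 2912 for LPS+EVs vs Control. The cause of these differences was not tested. Leaving out each library in turn gave 0 to 1 higher genes for LPS+EVs vs LPS (1 without LPS replicate 2, LOC120098595, adjusted p = 0.0417, named after its value was seen) and 1 to 4 higher and 1 to 4 lower lists. The higher lists were 3 without LPS replicate 1, 4 without LPS replicate 2, and 2 without LPS+EVs replicate 2 or 3, and the lower lists were 3 without LPS replicate 1 or 3, 2 without LPS+EVs replicate 1 and 4 without LPS+EVs replicate 2. Taking the 21 genes that are among the 10 most abundant of any library out of the totals left 33.4% of changed genes higher for LPS vs Control. At depths of 32148734 to 39407293 reads, 3 reads in a gene of 1 kilobase correspond to 0.076 to 0.093 FPKM, so depth limits genes near that level, and no alternative varied the depth.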

Other observations

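All tests of this part were chosen after the results were seen, except the counts over other splits of the samples and the tests of short transcripts and of a single LPS library by same-number differences, which were written down first. Pathways from KEGG, a collection that the plan did not include, held many genes of protein and DNA synthesis that fell with LPS. In the Ribosome pathway 123 of 152 tested genes fell and none rose in LPS vs Control (median log2 -0.77, camera adjusted p = 1.55e-13 over 309 pathways, adjusted p = 0.409 with an estimated correlation). In DNA replication 28 of 35 fell and none rose (median -1.60, adjusted p = 1.11e-08, adjusted p = 0.37 with an estimated correlation), and in Spliceosome 71 of 128 fell and 4 rose (median -0.53, adjusted p = 6.83e-05, adjusted p = 0.374 with an estimated correlation). In TNF signaling 41 of 101 genes rose and 12 fell (median 0.32, adjusted p = 1.52e-06, adjusted p = 0.305 with an estimated correlation). Camera called 44 pathways higher and 32 lower, and 0 of 309 with an estimated correlation, where the lowest adjusted p was 0.275. In LPS+EVs vs LPS it called 2 pathways higher and 1 lower, with Ribosome higher (median 0.22, adjusted p = 2.27e-19) and Ribosome biogenesis in eukaryotes lower (median -0.16, adjusted p = 0.0268, 0.0028 with the replicate block), each at adjusted p = 0.993 with an estimated correlation. In LPS+EVs vs Control it called 42 and 19 (0 with an estimated correlation in both comparisons, lowest adjusted p 0.993 and 0.268). With the replicate block 4 pathway calls were gained and 10 lost in LPS vs Control, 12 gained and 0 lost in LPS+EVs vs LPS, and 3 gained and 2 lost in LPS+EVs vs Control. Staphylococcus aureus infection was among those gained as higher in LPS+EVs vs LPS (median 0.21, adjusted p = 3.64e-05, 0.0725 without the block, adjusted p = 0.993 with an estimated correlation and no block).

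The libraries numbered 2 differed from those numbered 1 and 3 in the same way in all 3 groups. The MHC class II gene RT1-Bb was higher by log2 3.97 in Control, 5.53 in LPS and 4.97 in LPS+EVs, the invariant chain gene Cd74 by 1.64, 2.32 and 2.06, and the interferon-induced gene Ifit1 by 2.17, 2.17 and 2.20. Decorin (Dcn), a matrix gene of stromal cells, was lower by log2 -3.02, -3.63 and -2.62. In all 3 groups together 30 genes were at least 2-fold higher and 160 at least 2-fold lower in number 2 than in the mean of the other libraries, against 25 and 18 for number 1 and 43 and 12 for number 3.

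Mitochondrially encoded genes were lower in LPS+EVs than in LPS. A difference in scaling between libraries is argued against, since all other tested genes had a median log2 of -0.007 (quartiles -0.14 and 0.12), and a general loss of short transcripts, since 375 short nuclear genes had a median of 0.12 (quartiles -0.02 and 0.27). Lost or wrongly assigned reads of short mitochondrial genes stay open for the 6 genes of at most 700 bases (median -1.10), where ND4L (297 bases), ND3 (348) and ATP8 (204) had the largest falls, but are argued against for the 7 longer genes (median -0.54, quartiles -0.72 and -0.29). Variation between cultures that genes of 1 transcript share stays open, since the adjusted p with an estimated correlation was 0.316 (0.72 with the replicate block) and 3 pairs cannot give an exact p below 0.25. The pattern may also be a further step in the direction of the LPS change, because across the 13 genes the change with EVs followed the change with LPS (r = 0.66, and 0.60 without ND4L, genes not being independent and both changes sharing the LPS libraries with opposite sign), and an effect of the EVs, which the design names, stays open and untested.

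Cytosolic ribosomal protein genes showed the opposite: 69 of 73 fell in LPS vs Control (median log2 -0.95), and all 73 stood above 0 in LPS+EVs vs LPS (median 0.26), though none passed. A difference in scaling is argued against, since all other tested genes had a median of -0.009 (quartiles -0.14 and 0.11). A gene length bias stays open, since 321 other short nuclear genes had a median of 0.10. All 73 genes stayed above 0 with each library left out, at a median of at least 0.19 without 1 LPS library and at least 0.18 without 1 LPS+EVs library. This cannot decide on a single unusual library as the whole cause, because the library of the same number in the other group stays in. The same-number medians were 0.16, 0.05 and 0.59, with 68, 45 and 73 of 73 genes above 0. They leave some or all of the size open to 1 library, with LPS+EVs 3 nearer to its Control (-0.44) than LPS+EVs 1 and 2 (-0.80 and -0.74) and LPS 3 not apart from LPS 1 (-1 and -0.99). An effect of EVs stays a hypothesis.

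For the libraries numbered 2, sequencing depth is argued against, since that library had the fewest reads in 2 of the 3 groups but not in LPS+EVs. Alleles of RT1 unlike the reference are not the whole cause, since Cd74, which lies outside that gene family, was higher by at least 1.64. Fewer stromal cells in those cultures may be part of the cause, as 96.0% of the stromal marker genes (24 of 25) were lower in number 2 in all 3 groups, but the source of the interferon-induced genes was not tested. The groups of the design give no biological explanation, and apart from this mix of cells no biological explanation was tested.

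Each comparison of 3 libraries with 3 allows 10 splits, too few for a share under 0.05. Each other split puts unequal numbers of the compared groups on a side, so it keeps part of any group difference and adds the rest to the spread. For LPS vs Control and LPS+EVs vs Control its counts of genes and lists are therefore no measure of chance. For LPS vs Control the real split gave 4569 genes (1 of 10 splits gave as many) and the highest other split 0, and for LPS+EVs vs Control 4941 (1 of 10) and 0. For LPS+EVs vs LPS the real split gave 0 genes, which all 10 splits reach, and the highest other 1180, in the split of LPS 1, LPS 3 and LPS+EVs 3 from LPS 2, LPS+EVs 1 and LPS+EVs 2, which points to a structure of the samples. This split puts both libraries numbered 2 on 1 side, but 3 other splits that do so gave 0 genes (1142, 2656 and 1340 at an unadjusted p under 0.05). Splits that part all 3 pairs, as the real one does, gave 0. List calls with the preset correlation were as many in other splits: 18 in the real split of LPS vs Control (6 of 10 splits gave as many, highest other 22), 2 for LPS+EVs vs LPS (9 of 10, highest other 17, or 4 among splits that part 3 pairs) and 20 for LPS+EVs vs Control (4 of 10, highest other 22).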
